A study of Halobacterium salinarum NRC-1 with 8 samples.

How the data were processed

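RNA of a Halobacterium salinarum NRC-1 strain that lacks ura3 and htlD was measured on 8 two-colour arrays. NRC-1 is a halophilic archaeon. The ura3 deletion is the usual background for knockouts in this organism, because ura3 serves as the marker. Cultures of 50 mL in 125 mL flasks were grown in rich medium to mid-log phase. High oxygen meant shaking at 210 rpm and low oxygen meant 100 rpm in a closed flask, each in light and in the dark, per the labels. Each of the 4 conditions gave 1 RNA sample, and each RNA was hybridised on 2 arrays with the dyes exchanged, against one standard NRC-1 reference from mid-log cells at an OD600 of 0.5 to 0.6. Replicate 1 of each condition carried the culture in Alexa 532 and replicate 2 in Alexa 647.

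Per the file headers, each scanner file holds the mean spot intensity and the median local background intensity of both dyes, in a high and a low scan, with no background subtraction recorded. The same files hold a deposited spot confidence score per dye and scan. The deposited value table holds log10 ratios made by the authors; set against the scanner values, its columns follow log10 of Alexa 532 over Alexa 647 on all 8 arrays, not turned for the dye exchange. The correlation with the high scan was 0.621 to 0.905 when the table's rows were read along the slide rows, and 0.0503 to 0.236 in the order of the scanner files. The column medians on the log10 scale were 0.0259 and 0.1 for high oxygen in light, 0.0797 and 0.0936 for high oxygen in the dark, 0.0225 and 0.0953 for low oxygen in light, and 0.0422 and 0.0757 for low oxygen in the dark. So the columns are not centred; the background step, the use of the 2 scans and the normalization behind them are not given in the sources used here. Some spots are empty in that table, and the reason is not given.

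From the scanner files, the high-scan mean was used, and spots above 40000 were replaced through a robust linear fit of the low scan on the high scan between 8000 and 35000 (MASS 7.3.60.0.1, R 4.3.3). Between 108 and 1214 spots per channel lay above 40000. Background was corrected by normexp with an offset of 50, and log2 ratios were normalized by loess within each array (limma 3.58.1). Ratios were turned to culture over reference on every array. Spots with a confidence under 50 that were not above 40000 were left out, 6 spots over all arrays. Each array has 10752 spots, which are 4 spots of each of 2688 probes, a grouping that the given gene table bears out for all its 133 named genes (532 spots); spots of one probe were averaged. How the scans were joined and the spots grouped was chosen after the data were seen. The other choices were made before the data were examined, unless said otherwise.

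Gene names came from the platform annotation, which gives 1 symbol to 133 probes, several to 0 and none to 2555. Names can be old, and which of the unnamed probes are controls is not known, so none were left out. A gene table of another strain was at hand and was not used, and no genome coordinates are given. A probe was called above background on an array where its median ratio of spot to local background was over 1.5 in the channel concerned. Across arrays and dyes, 48 to 86.5% of spots were above that ratio. The number of arrays limits the precision.

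The 2 arrays of an RNA were averaged and counted as 1 replicate, so each test used 4 values. limma's linear model with empirical Bayes moderation was fitted with additive oxygen and light terms, with Benjamini-Hochberg adjustment over all probes and a threshold of 0.05. The fit left 1 residual degree of freedom, which is the interaction, and a prior of 3.413 degrees of freedom. The interaction itself therefore has values and no test. The grand mean against 0 compares the cultures with the reference and leaves out the reference's own spread. No label or file gives a slide or scan date, so no batch was tested. With 1 RNA per condition, p-values and standard errors describe only these samples, and they rest on the interaction and the prior. Spread between the samples that goes with oxygen or light is left out of them, also for the grand mean.

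Gene lists were 30 fixed sets; 18 had a named member and 10 had at least 3, with 63 genes together. These were tested by camera with a preset correlation of 0.01, with an estimated correlation and by fry. The estimated correlation and its test rest on the 1 residual degree of freedom, so hardly any list could pass that version. A miss there is no evidence against a list. The genes named in the text were fixed by rule. For oxygen and for light they are up to 12 per direction with the largest difference among genes past the threshold, filled up with genes whose difference has the same sign in all 4 array-level differences. For the reference they are up to 6 per direction past the threshold with one sign on all 8 arrays, and for the interaction 5 per direction with one sign in both dye orientations. A fixed set of light, oxygen and transducer genes is named wherever measured, with up to 4 members of each list.

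The steps were tested on simulated data with 4 values for each of 2688 probes, drawn from the fitted means and variance prior, of which 200 were changed, over 20 draws. For oxygen, 47.8% of the probes changed 1.5-fold and 93.1% of those changed 2-fold were recovered, with 11.2 false calls on average. For light the shares were 39.1% and 91%, with 8.5 false calls, and for the reference 97.2% and 99.5%, with 15.4 false calls. A simulated oxygen shift of 1 log2 unit in a list of 10 probes was called in 100% of 20 draws. The tested lists had oxygen medians of up to 0.178, and the simulation says nothing on shifts of that size. Its noise was independent between probes, with no dye effect and no dependence on signal intensity, so the recovered shares need not hold for these arrays.

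The alternatives were no or plain background subtraction, a normexp offset of 10, median centring, scaling between arrays, Aquantile, the authors' values, leaving out probes under the 0.25 quantile of mean intensity, all 8 arrays with the RNA as a random block and a dye term, each dye orientation alone, leaving out each array and each RNA, each factor alone, empirical Bayes with an intensity trend and robust estimation, an adjusted p of 0.10, and the median over spots. Alternatives chosen after seeing the data were the high or the low scan alone, loess within print blocks (span 0.4), the authors' values centred on each array's median, only probes above background in both channels on all 8 arrays, and adjustment over the named genes alone. Figures were drawn with matplotlib 3.10.9.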

Results

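Gene expression was measured in knockout cultures of Halobacterium salinarum NRC-1 that lacked ura3 and htlD, grown at high or low oxygen and in light or darkness. The design crossed oxygen with light in this strain. There were 4 RNA samples, 1 per condition, each on 2 arrays with exchanged dyes and each against the same NRC-1 reference. All values below are log2 ratios of culture over reference or differences between them, with the standard error of the fit and n = 4 RNA samples. Median spot signals in the high scan ran from 1502 to 7172, at 1.45 to 3.86 times the local background. Of 2688 probes, 133 carried a gene name. The arrays of one RNA with exchanged dyes correlated weakly across probes, with r from -0.316 to 0.15, while arrays of different RNA samples with the same dye order had r from 0.269 to 0.689. Probes are not independent replicates.

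The deletion was checked first through pyrF, the orotidine-5'-phosphate decarboxylase gene of uracil synthesis that is called ura3 in this background. The pyrF ratio was lower in the cultures than in the reference on 8 of 8 arrays, between -1.29 and -0.038. By condition it was -0.85 at high oxygen in light, -0.74 at high oxygen in the dark, -0.68 at low oxygen in light and -0.45 at low oxygen in the dark. The mean was -0.68 ± 0.050 (SE, n = 4; adjusted p = 0.0172 by limma), and it ranked 8 from the lowest of 2688 probes. Leaving out high oxygen dark replicate 1 or 2, low oxygen light replicate 2 or low oxygen dark replicate 1 or 2 kept the sign (-0.82 to -0.54) and ended the call, with an adjusted p of 0.0523 to 0.131. Plain background subtraction also ended the call (-1.16, adjusted p = 0.106). The mean was -0.35 with the culture in Alexa 532, -1.01 in Alexa 647 and -0.32 in the low scan, and pyrF was called in 20 of 26 alternatives. The probe was above background on 4 of 4 culture channels at low oxygen, 1 of 2 at high oxygen in the dark, 0 of 2 at high oxygen in light and 6 of 8 reference channels. Signal at the pyrF probe was thus measured above local background in every low-oxygen culture, and near background at high oxygen the ratios are not exact. Whether the probe lies in the deleted part, or picks up other transcripts, is not known here. No probe carried the name htlD, which was not analysed here.

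The comparison with the reference asked which transcripts differed between the knockout cultures and the NRC-1 standard. The ribosomal protein genes rpl12p (-0.62 ± 0.055, adjusted p = 0.0198) and rpmC (-0.49 ± 0.071, adjusted p = 0.0211) were lower on 8 of 8 arrays. So were sucC of succinyl-CoA synthetase (-0.41 ± 0.048, adjusted p = 0.0198), the DNA gyrase subunit gene gyrA (-0.39 ± 0.059, adjusted p = 0.0216) and the citrate synthase gene citZ (-0.33 ± 0.050, adjusted p = 0.0219). Among named genes, the highest ratio with one sign on all 8 arrays belonged to arcC, the carbamate kinase gene of arginine fermentation (0.36 ± 0.048, adjusted p = 0.0200). It was followed by the transducer gene htr18 (0.34 ± 0.053, adjusted p = 0.0219), above background on 6 of 8 culture channels and 5 of 8 reference channels, and by the chemotaxis response regulator gene cheY (0.21 ± 0.048, adjusted p = 0.0407). Over 26 alternatives htr18 ranged from 0.064 in the authors' values to 0.77 with plain background subtraction and was called in 17, with an adjusted p of up to 0.441.

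Among genes named in advance, bat, the activator gene of bacteriorhodopsin expression, was higher in the cultures (0.26 ± 0.051, adjusted p = 0.0304) on 7 of 8 arrays. Its probe was above background on 5 culture and 3 reference channels and its value was -0.024 in the authors' values, with a call in 11 of 25 alternatives. The iron-storage gene dpsA was at 0.18 ± 0.050 and missed the threshold (adjusted p = 0.0584), as did the arginine deiminase gene arcA at 0.10 ± 0.059 (adjusted p = 0.244). The list of sensory rhodopsins and transducers has 10 genes, among them the halorhodopsin gene hop, which is neither. Of these 10, 7 had ratios above 0 (8 with median centring), with a median of 0.0912 and 1 called, htr18, 1 also when adjusted over the list alone (camera adjusted p = 0.363). Both sensory rhodopsin genes named in advance and their transducers were not called. The values were sop1 at 0.078 ± 0.050, sop2 at -0.065 ± 0.049 (0.00051 with median centring in place of loess and 0.022 without high oxygen dark replicate 1), htr1 at 0.080 ± 0.052 and htr2 at -0.080 ± 0.048, with adjusted p from 0.262 to 0.362. All 6 named genes of the TCA cycle had ratios below 0 (5 of 6 with median centring), and 3 of them were called, or 4 when adjusted over the list alone. The list missed the threshold by camera (adjusted p = 0.053). With an estimated correlation in camera the adjusted p was 0.711, in a version that hardly any list could pass with 1 residual degree of freedom. All 4 chemotaxis genes had ratios above 0, of which cheY was called, 1 also when adjusted over the list alone (camera adjusted p = 0.279, and 0.711 with an estimated correlation). No other list passed by camera. None passed with an estimated correlation or by fry, where hardly any list could.

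In all, 749 of 2688 probes differed from the reference by limma, 342 higher and 407 lower. Of the 133 named genes 26 were called, 7 higher and 19 lower, or 24 when adjusted over the named genes alone. Other named calls were argH on the higher side, and gdhA1, phoU, cbiT, gdhA2, hemA, mdh, cbiG, speB, thiL, thiD, lysS and gyrB on the lower side. The calls of purB, nadA and proS rested on signal near background, with culture channels above it on 2, 2 and 4 and reference channels on 0, 2 and 3 of 8 arrays. Although its mean was on the higher side, purB was lower than the reference on 6 of 8 arrays, and no direction is read from these 3 calls. Among unnamed probes, probe_803 was higher (1.05, adjusted p = 0.0138) and probe_2581 lower (-1.33, adjusted p = 0.00659), each on 8 of 8 arrays, with culture channels above background on 8 and 6 of 8 arrays. The count was 0 with plain background subtraction and without high oxygen dark replicate 1, high oxygen dark replicate 2 or low oxygen light replicate 2. It was 7 and 1 without low oxygen dark replicate 1 and 2, and 417 without high oxygen light replicate 2. Every gene given above with its value as called, pyrF and bat among them, lost its call without any one of the first 5 of these arrays. So did bat without high oxygen light replicate 2 (adjusted p = 0.0608, of 0.0302 to 0.188 without single arrays), and cheY lost its call without any of the 8 (0.0534 to 0.163). The signs of these genes stayed. Leaving out 1 array also ends the dye balance of its RNA, so lost calls need not mean that the array itself was influential. Without any of the first 5 arrays arcC was at 0.334 to 0.394, sucC at -0.434 to -0.388 and bat at 0.198 to 0.316.

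**Figure D1:**
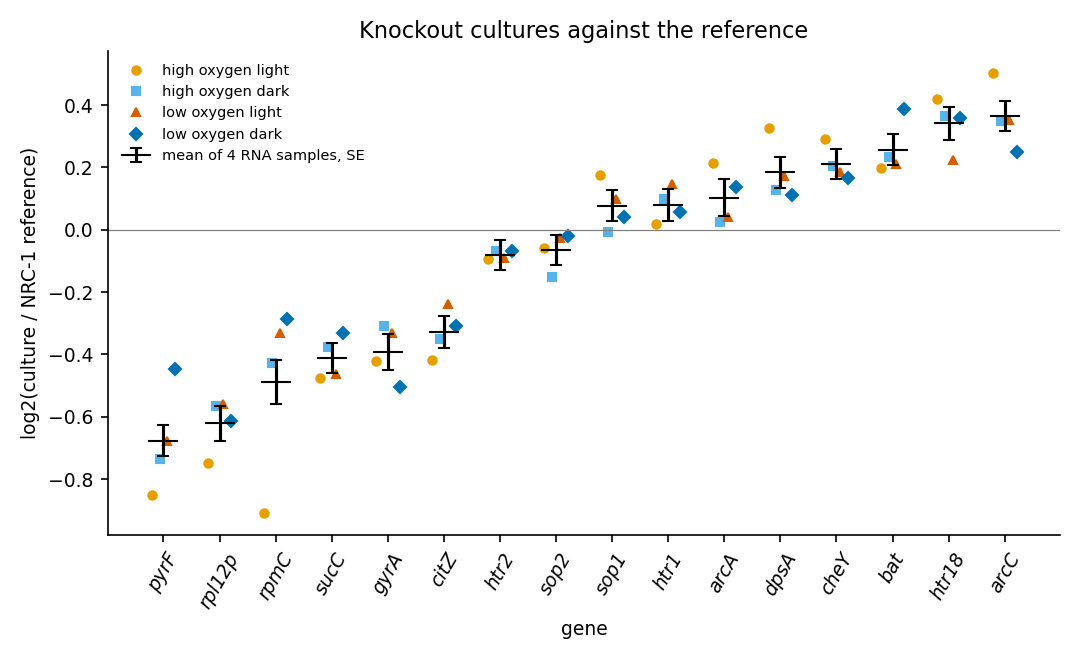
Log2 ratios of culture over the NRC-1 reference (vertical axis) for the genes named in this comparison (horizontal axis). A marker stands for each of the 4 RNA samples (mean of 2 dye-exchanged arrays). A black bar gives the mean with the standard error of the fit, which leaves out spread that goes with oxygen or light. The pyrF markers lie between -0.85 and -0.45, all below 0, and the arcC markers between 0.25 and 0.50, all above 0.

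The oxygen comparison set cultures at low oxygen against those at high oxygen. The largest difference of a named gene above background on all arrays was that of gdhA1, a glutamate dehydrogenase gene, at 0.58 ± 0.10 (1.49-fold, n = 4), with 0.66 in the light pair and 0.49 in the dark pair. Other genes above background on all culture channels, with one sign in all 4 array-level differences and higher values at low oxygen, were rpmC of the ribosome (0.36 ± 0.14), the seryl-tRNA synthetase gene serS (0.35 ± 0.098), pan1 of the proteasome-activating ATPase (0.33 ± 0.10), the methionine aminopeptidase gene map (0.28 ± 0.10), the isoleucyl-tRNA synthetase gene ileS (0.22 ± 0.099) and psmA of the proteasome core (0.21 ± 0.096). The agmatinase gene speB was at 0.26 ± 0.11, the phosphonate transporter gene phnE at 0.23 ± 0.11 and the heme synthesis gene hemA at 0.20 ± 0.10. None of these differences passed the threshold (adjusted p from 0.521 to 0.645 by limma). One sign in all 4 array-level differences was found for 383 of 2688 probes (14.2%), where independent signs would give 12.5%. Such agreement is therefore little support for a single gene.

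With lower values at low oxygen, the cysteinyl-tRNA synthetase gene cysS was at -0.30 ± 0.098 and the menaquinone synthesis gene menD at -0.27 ± 0.10. They were followed by gdhB, a second glutamate dehydrogenase gene (-0.16 ± 0.098), the cobalamin genes cbiQ (-0.13 ± 0.096) and cobN (-0.11 ± 0.10), and the chemotaxis genes cheR (-0.12 ± 0.096) and cheA (-0.083 ± 0.096). These were the 7 genes of that direction with one sign in all 4 array-level differences, and none passed the threshold (adjusted p from 0.577 to 0.830). The cysS probe was above background on 3 of 4 culture channels at low and 4 of 4 at high oxygen, and on 4 of 8 reference channels. The rule also chose pyrF and the amidotransferase gene gatC with higher values at low oxygen, but their probes were above background on 0 of 2 culture channels at high oxygen in light, and their differences are not described here. Leaving out 1 array turned the sign of cysS (0.010 without high oxygen dark replicate 2 and 0.059 without low oxygen dark replicate 1) and of cobN (0.0054 without high oxygen light replicate 1).

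By group, all 4 named genes of the proteasome list had higher values at low oxygen, led by pan1 and psmA, with a list median of 0.178 and 0 called, 0 also when adjusted over the list alone (camera adjusted p = 0.255, and 0.836 with an estimated correlation). All 4 DNA repair genes (mutL, 0.21 ± 0.11), all 5 pyrimidine genes (carB, 0.16 ± 0.12), all 7 purine genes (purM, 0.11 ± 0.11, and purD, 0.093 ± 0.11) and all 6 TCA cycle genes (sdhC, 0.13 ± 0.097, and citZ, 0.11 ± 0.10) also lay above 0. The pyrimidine count includes pyrF, whose probe was near background at high oxygen, and the purine count purB, whose probe was near background. No direction is read from either. With other scalings 1 member lay on the other side in the proteasome, DNA repair, purine and TCA cycle lists, and none in the pyrimidine and chemotaxis lists. The chemotaxis genes, 4 of 4 below 0, had a median of -0.1. The 10 genes of the sensory rhodopsin and transducer list, hop included, divided into 5 above and 5 below 0, but into 2 and 8 with loess within print blocks and 3 and 7 with median centring, with htr4 at -0.15 ± 0.096 (0.044 without low oxygen dark replicate 2). Amino acid synthesis divided into 8 and 8 (11 above and 5 below within print blocks), cobalamin into 2 and 2, and glycolysis into 1 above and 2 below (2 and 1 with scaling between arrays). No member of any list was called, over all probes or adjusted over the list alone. None of the 10 lists passed by camera, the lowest adjusted p being 0.255. None passed with an estimated correlation or by fry either, where hardly any list could with 1 residual degree of freedom. Without background subtraction and in the authors' values the proteasome list passed (adjusted p = 0.0263 and 0.00524, in a range of 0.00524 to 0.916 for the lowest list over the alternatives).

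Over all 2688 probes, limma called 0 for oxygen, with 224 at an unadjusted p under 0.05 where 134.4 were expected by chance. Adjusted over the 133 named genes alone, 0 were called, with 9 at an unadjusted p under 0.05 where 6.65 were expected by chance. The low minus high oxygen differences of the light pair and the dark pair had r = 0.151 across probes (rho = 0.175), between -0.167 without high oxygen dark replicate 2 and 0.294 without high oxygen dark replicate 1. Over the 1154 probes above background on all arrays r was 0.383, and with the culture in Alexa 647 it was 0.485. Taken across dye orientations, r was -0.269 and -0.301 over all probes, and 0.292 and -0.1 over those above background. Other settings made calls: 34 probes without background subtraction, 48 with an intensity trend and robust estimation, 49 among the 1154 probes above background on all arrays, 7 in the authors' values and 9 without high oxygen light replicate 1. In 5 of 29 alternatives gdhA1 was called, with a positive difference in all 29 (0.41 to 0.76, adjusted p from 1.68e-11 to 1). Of the other genes named for oxygen, rpmC was called in 3, serS, pan1 and speB in 2 each and map in 1 of 29, each with a positive difference in all 29. Several of the 29 leave a gene's difference unchanged by construction, and the rule fixed its sign in each dye orientation. The shared sign is therefore no independent support.

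**Figure D2:**
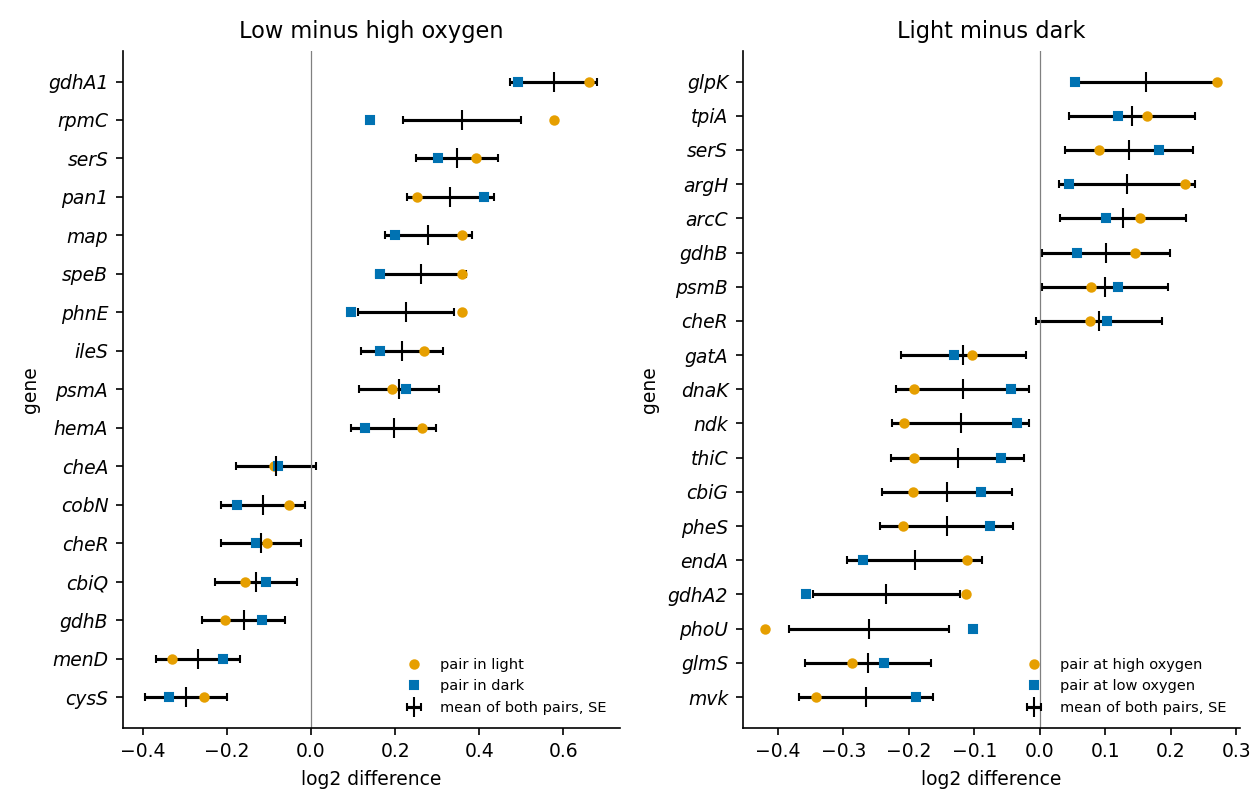
Log2 differences (horizontal axes) of the genes named for oxygen (left, low minus high) and for light (right, light minus dark), leaving out genes whose culture channel was above background on 0 of 2 arrays in any of the 4 conditions; circles and squares are the 2 culture pairs and black bars the mean with its standard error. At low oxygen gdhA1 was higher by 0.66 and 0.49 in its pairs, and in light mvk was at -0.34 and -0.19, neither past the threshold.

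The light comparison set cultures in light against those in the dark. Among genes above background on all culture channels and with one sign in all 4 array-level differences, those with higher values in light were the glycerol kinase gene glpK (0.16 ± 0.11, n = 4), the triosephosphate isomerase gene tpiA (0.14 ± 0.096), serS (0.14 ± 0.098), the argininosuccinate lyase gene argH (0.13 ± 0.10), arcC (0.13 ± 0.096), gdhB (0.10 ± 0.098), psmB of the proteasome (0.099 ± 0.096) and cheR (0.090 ± 0.096). None passed the threshold (adjusted p from 0.686 to 0.827). For light, 511 of 2688 probes (19%) had one sign in all 4 array-level differences, where independent signs would give 12.5%. The glpK probe was above background on 5 of 8 reference channels only. The sign turned for argH without high oxygen dark replicate 1 (-0.029) and for arcC without high oxygen light replicate 1 (-0.0073).

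Lower values in light were found for the mevalonate kinase gene mvk (-0.27 ± 0.10), the glucosamine-6-phosphate synthase gene glmS (-0.26 ± 0.096), the phosphate regulator gene phoU (-0.26 ± 0.12) and gdhA2, a further glutamate dehydrogenase gene (-0.23 ± 0.11). Below these came the tRNA endonuclease gene endA (-0.19 ± 0.10), the phenylalanyl-tRNA synthetase gene pheS (-0.14 ± 0.10), the cobalamin gene cbiG (-0.14 ± 0.099), the thiamine synthesis gene thiC (-0.13 ± 0.10), the nucleoside diphosphate kinase gene ndk (-0.12 ± 0.10), the chaperone gene dnaK (-0.12 ± 0.10) and the amidotransferase gene gatA (-0.12 ± 0.096). None of them passed (adjusted p from 0.355 to 0.777), and endA was at 0.11 without low oxygen dark replicate 2. The rule also chose the prolyl-tRNA synthetase gene proS, purB of purine synthesis and nadA of NAD synthesis, none past the threshold. The purB and nadA probes were above background on 0 of 4 culture channels in light and 2 of 4 in the dark. The proS probe was above background on 0 of 2 culture channels at high oxygen in the dark and on 1 of 2 in each light condition, and the differences of these 3 genes are not described here.

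By group, all 3 glycolysis genes had higher values in light (tpiA, and ppsA at 0.094 ± 0.11), as did all 4 chemotaxis genes (median 0.0536). All 5 pyrimidine genes had lower values in light (carA, -0.11 ± 0.097), as did 6 of 7 purine genes and 5 of 6 TCA cycle genes (sucC, -0.11 ± 0.096). Among those counted are purB, near background in light, and pyrF, near background in light at high oxygen, and no direction is read from either. The sensory rhodopsin and transducer list, hop included, divided into 5 and 5, DNA repair into 2 and 2 (mutL, -0.22 ± 0.11), proteasome into 2 and 2, cobalamin into 2 and 2 (cbiT, -0.16 ± 0.13), and amino acid synthesis into 7 above and 9 below (aroC, 0.26 ± 0.15). With other scalings 1 member lay on the other side in the glycolysis, chemotaxis and pyrimidine lists, and with median centring 4 of 7 purine genes had higher values in light. Other scalings also gave 6 and 4 genes of the sensory rhodopsin and transducer list, 1 and 3 cobalamin genes and 8 and 8 amino acid synthesis genes above and below 0. No list member was called over all probes, and purB was the 1 member called when adjusted over its list alone. No list passed by camera (lowest adjusted p = 0.765). None passed with an estimated correlation or by fry either, where hardly any list could.

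For light, limma called 0 of 2688 probes, with 370 at an unadjusted p under 0.05 where 134.4 were expected by chance. Adjusted over the 133 named genes alone, 2 were called, purB and gatC, neither above background on any culture channel in light, with 4 at an unadjusted p under 0.05 where 6.65 were expected by chance. The differences at high and at low oxygen had r = 0.404 across probes (rho = 0.292), between -0.192 without high oxygen dark replicate 1 and 0.51 without high oxygen dark replicate 2. The bat, sop1, sop2, htr1, htr2, arcA and dpsA genes had light minus dark values from -0.11 to 0.13 and low minus high oxygen values from -0.085 to 0.085, none called. The bat probe was above background on 0 of 2 culture channels at low oxygen in light. Differences were wider in dim probes: the light differences had an SD of 0.0961 over the 1154 probes above background on all arrays, against 0.419 over the 720 probes above background in at most 8 of 16 channels. For light, other settings called 116 probes without background subtraction, 39 with an intensity trend and robust estimation, 8 among the 1154 probes above background, 224 in the authors' values, 134 on the arrays with the culture in Alexa 532 and 243 without high oxygen light replicate 1. Of the genes named for light, phoU was called in 1 of 29 alternatives (adjusted p from 0.0339 to 0.995), proS in 3 of 26 (0.000271 to 0.995) and purB in 6 of 26 (2.1e-05 to 0.995).

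**Figure D3:**
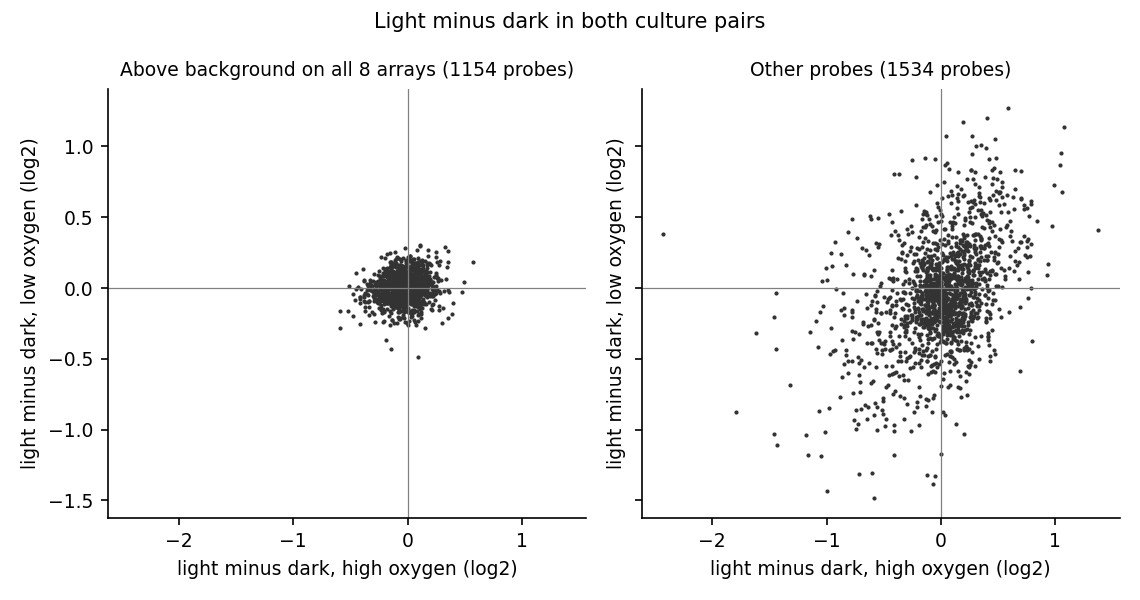
Light minus dark differences (log2) at high oxygen (horizontal axes) against those at low oxygen (vertical axes), 1 dot per probe, for the 1154 probes above background on all 8 arrays (left) and the other 1534 probes (right). The left cloud is compact with r = 0.157, and the right cloud is wider with r = 0.433.

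For the interaction, the difference between low and high oxygen in light was set against that in the dark. It was higher in light for rpmC (0.58 in light and 0.14 in the dark), secY of the protein translocase (0.34 and -0.015) and the cobalamin gene cbiT (0.26 and -0.088). It was lower in light for mch (-0.34 and 0.39), the excision repair gene uvrA (-0.12 and 0.51), the chorismate synthase gene aroC (-0.31 and 0.17) and the glycyl-tRNA synthetase gene glyS (-0.064 and 0.35). The interaction was thus 0.44 for rpmC, 0.35 for secY, 0.35 for cbiT, -0.73 for mch, -0.63 for uvrA, -0.48 for aroC and -0.42 for glyS. The sign was the same in both dye orientations, as the rule required. The probes of hutG and hutI of histidine degradation and of gatC, also chosen by rule, were above background on 1, 1 and 2 of 8 culture channels, and no value is given for them. The glyS probe was above background on 8 of 8 culture channels but on 5 of 8 reference channels. With 1 RNA per condition these interaction values had no test. Across probes, the SD of the interaction divided by 2 was 0.159, against 0.185 for oxygen and 0.244 for light. Over the 1154 probes above background on all arrays the order of oxygen and light turned, with 0.083 for the interaction divided by 2, 0.122 for oxygen and 0.0961 for light.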

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

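The count over all named genes was chosen after the results were seen, as was leaving out hutG, whose probe was above background on 1 of 8 culture channels. Among the 10 genes chosen for the largest interaction with one sign in both dye orientations, 5 are given below, for which both arrays of one culture pair gave a difference opposite in sign to both arrays of the other pair; choosing them by their interaction favours this. With 1 RNA per condition, these differences between pairs were not tested. Among all 133 named genes, 11 were opposite in this way for oxygen and 19 for light, where 4 independent signs would give 16.625 for each. The array-level differences were not independent, with r for oxygen of 0.287 and 0.485 within dye orientations and -0.269 and -0.301 across them. So 16.625 is not an exact chance value.

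For light minus dark, secY was at -0.21 at high and 0.14 at low oxygen, a difference of 0.351. The value of mch was 0.41 at high and -0.32 at low oxygen, a difference of -0.731. That of uvrA was 0.20 at high and -0.43 at low oxygen, a difference of -0.628. For cbiT it was -0.33 at high and 0.018 at low oxygen, a difference of 0.349. Its values at low oxygen were 0.030 and 0.0049 in the 2 dye orientations, too near 0 to read a direction. For low minus high oxygen, cbiT was at 0.26 in light and -0.088 in the dark, the latter from -0.165 and -0.0105 in the 2 dye orientations. The difference of 0.349 is the same value by construction and no further observation. The value of aroC was -0.31 in light and 0.17 in the dark, a difference of -0.484. All these differences are the interaction values given above. The probes of secY, cbiT and aroC were above background on 8 of 8 culture channels, those of mch and uvrA on 7 of 8. No technical or biological explanation was tested for single genes.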

How the results depend on the processing

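The high scan alone, the low scan alone, loess within print blocks, the centred authors' values, the probes above background alone and the adjustment over named genes alone were chosen after seeing the data. The lists for light had 0 calls in all 27 alternatives. Aquantile scaling leaves the ratios as they are by construction, so it tests nothing. Signal over background limits what can be measured, since 1154 of 2688 probes were above background in both channels on all 8 arrays. Among values of single genes, 769 for light, 716 for oxygen and 328 for the reference kept their direction and their side of the threshold; 10, 15 and 12 passed it only under an alternative, 79 for the reference no longer passed it, and 19, 14 and 9 turned sign. Where an array was left out, the RNA stood on 1 array and was assumed to vary like the others. Its dye balance was lost, so a dye effect enters the values without single arrays. It cannot be told apart there from an influence of the array itself. Without a whole RNA, the values are those of the remaining pair and no test was run. Unless stated, the cause of a change below was not tested.

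Probes changed by oxygen, 0 in the reported analysis, numbered 34 without background subtraction, 7 in the authors' values, 7 on the arrays with the culture in Alexa 532, 48 with trend and robust estimation, 13 in the centred authors' values, 49 among probes above background and 0 to 9 without single arrays (9 without high oxygen light replicate 1). Probes changed by light, also 0, numbered 116, 224, 134, 39, 92 and 8 under the same alternatives in that order, 2 when adjusted over the named genes alone, where fewer probes are tested, and 0 to 243 without single arrays (243 without high oxygen light replicate 1). Probes differing from the reference, 749, numbered 1131 without background subtraction, 0 with plain subtraction, 1142 in the authors' values, 1262 with 8 arrays, the RNA as a random block and a dye term (consensus correlation -0.454), 368 on the arrays with the culture in Alexa 647, 1248 with trend and robust estimation, 436 in the low scan and 0 to 679 without single arrays. Of the called probes 45.7% were higher, against 16.4% in the authors' values, 44.1% once those were centred, 37% with median centring and 55.8% without the dimmest probes. One list changed with oxygen, against 0, without background subtraction (1), in the authors' values (1) and in these centred (1), each time the proteasome and proteases.

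The mean pyrF ratio of -0.68 was -0.41 without background subtraction, -1.16 with plain subtraction, -0.347 with the culture in Alexa 532 and -1.01 in Alexa 647, -0.324 in the low scan, -0.474 in the centred authors' values and -0.815 to -0.54 without single arrays. The SD of the interaction divided by 2, 0.159, was 0.0896 without background subtraction, 0.319 with plain subtraction, 0.174 with an offset of 10, 0.169 with median centring, 0.11 in the authors' values and 0.11 in these centred, 0.118 without the dimmest probes, 0.225 and 0.218 with the culture in Alexa 532 and 647, 0.168 with the median over spots, 0.192 in the low scan, 0.083 among probes above background and 0.181 to 0.252 without single arrays. The correlation of oxygen differences between pairs, 0.151, was 0.485 with the culture in Alexa 647, 0.383 among probes above background and -0.167 to 0.294 without single arrays. That of light differences, 0.404, was 0.0711 with plain subtraction, 0.11 with the culture in Alexa 647 and -0.192 to 0.51 without single arrays.

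The sign of single genes turned as follows; the probes of gatC, nadA and pyrF were above background on 0 of 2 culture channels in at least 1 condition, so the values of gatC and nadA, and those of pyrF for oxygen, are ratios near background that are given only to show their spread, with no size or direction read from them. In the authors' values, gatC was at -0.0298 for oxygen, nadA at -0.173 for light and bat at -0.0238 against the reference. In the centred authors' values, gatC was at -0.0148 for oxygen, and for light nadA was at -0.0896, ndk at 0.0352, gatA at 0.0471 and sucC at 0.0672, with sop2 at 0.0256 against the reference. In the low scan, cysS was at 0.242, menD at 0.0534 and purM at -0.0304 for oxygen, and nadA at -0.0715, glpK at -0.228, serS at -0.0629 and gatA at 0.0818 for light. In the high scan, gdhB was at 0.095 for oxygen and -0.0185 for light, thiC at 0.00173 and ppsA at -0.0139 for light, and dpsA at -0.077 against the reference. With plain subtraction, mutL was at -0.0028 for oxygen and 0.0181 for light. With the culture in Alexa 532, sop1 was at -0.12 and htr1 at -0.00432 against the reference, and in Alexa 647 sop2 was at 0.119, htr2 at 0.0082 and, for light, sucC at 0.0181. With median centring, sop2 was at 0.000507 against the reference. Without single arrays the ranges were -0.472 to 1.47 for gatC, -0.0441 to 0.505 for pyrF, -0.651 to 0.0588 for cysS, -0.233 to 0.00537 for cobN and -0.334 to 0.044 for htr4 for oxygen. For light they were -0.0781 to 0.424 for nadA, -0.0286 to 0.295 for argH, -0.00732 to 0.261 for arcC and -0.488 to 0.106 for endA, and against the reference -0.151 to 0.022 for sop2.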

Other observations

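The test of position against the same side of the slide, the test of a probe-specific dye effect and both tests of a dye effect alone were chosen after the results were seen. Glutamate dehydrogenase genes, looked at after their values were seen, differed against the reference: gdhA1 was lower in the cultures (-0.45 ± 0.052, adjusted p = 0.0198 by limma, n = 4) on 7 of 8 arrays and gdhA2 as well (-0.30 ± 0.056, adjusted p = 0.0290) on 7 of 8, while gdhB missed the threshold at 0.16 (adjusted p = 0.0784). The gdhA1 ratio was uneven between conditions. It was -0.86 in light and -0.62 in the dark at high oxygen, but -0.20 and -0.13 at low oxygen. The standard error of its mean leaves this oxygen difference out. No probe was called without high oxygen dark replicate 1 or 2 or low oxygen light replicate 2.

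The light minus dark differences at high and at low oxygen correlated across probes with r = 0.404. Over the 1154 probes above background on all arrays r was 0.157, against 0.515 over the 720 probes above background in at most 8 of 16 channels; signal near background may contribute, as 0.157 lies between the bounds of 0.1 and 0.3 set for it. A dye effect equal on all arrays cancels in these differences, but one that varies between arrays does not: taken from opposite dye orientations the mean r was 0.124 (0.0519 and 0.0512 over the probes above background), against 0.47 and 0.11 within Alexa 532 and 647, and lies between the bounds of 0.1 and 0.2 for a dye bias of single arrays. Taken from opposite sides of the slide it was 0.256 (0.229 and 0.282), which is 95.5% of that within one side (0.270 and 0.265) and argues against position that differs between the sides, though it lies under the bound of 0.3 set before, which r within one side did not reach either. Signal near background, dye bias that varies between arrays and position effects alike on both sides cannot be told apart from a shared response to light, which stays open as untested.

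The 2 arrays of one RNA with exchanged dyes correlated at -0.316 to 0.15. The differences between exchanged arrays correlated between RNA samples with a median r of 0.408 (0.272 to 0.727), where a dye effect specific to each probe needs more than 0.3. That bound was set after the array correlations were seen, and this r largely follows from them, so it is no separate support. A dye effect that each probe carries across arrays is a candidate explanation, as a hypothesis found on these data. The means of the exchanged arrays also correlated between RNA samples, with a median r of 0.471, and they share the one reference. No biological explanation was tested.

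For the 749 probes that differed from the reference, of which 250 were above background on all arrays, a dye effect of equal size in both orientations cancels in the mean by design, and one that varies between arrays could remain; the mean ratios of the 2 orientations correlated at r = 0.00169 over all probes and 0.359 over those above background, which does not measure what remains. Of the 749, 85% (against 55.1% of all probes) had one sign in both orientations, but that test was void, since choosing probes by the mean of both orientations favours equal signs, so its bound of 80% was set wrongly. Among probes above background called in one orientation, 77.3% had the same sign in the other (143 of 185 and 109 of 141), which argues against a dye effect alone for that group only. Among the other probes the share was 51.7% (357 of 684 and 114 of 227), between the bounds of 50 and 70%, a share of single orientations that says nothing on the mean, so for them a dye effect that varies between arrays stays open. A difference of strain, growth state or medium from the reference stays open as untested.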
